A study of Homo sapiens with 6 samples.

How the data were processed

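Total RNA of H226 lung squamous carcinoma cells was hybridised to 6 Affymetrix HuGene 1.0 ST arrays, per the labels and the design text. The arrays fall into 3 groups of 2 by their titles: untreated cells with the p63 shRNA off (control), cells with the shRNA off given 10 µM Nutlin-3 for 12 h (Nutlin-3), and cells given 1 µg/mL doxycycline for 48 h, which turns the shRNA on (shp63 ON). The deposited table holds log2 probe set intensities that the authors had normalized between arrays. The log2 scale is read from the values, which run from 2.94 to 14.9 with array medians of 6.57 to 6.70 over all probe sets. The submitters' processing notes name Partek, with the version not given, and the design text names Partek and an analysis of variance for differential expression. The background correction, the normalization and the summary of probes into probe sets are not given in the sources used here. Arrays give no read depth, and their number limits the precision.

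The table has 32321 probe sets. Of these, 19158 name 1 gene in the platform annotation, 1388 name several and 11775 name none. Only probe sets naming 1 gene were used, giving 18404 genes. Of those probe sets 19128 matched a current gene by Entrez identifier, and 0 symbols changed. Where a gene had several probe sets (637 genes), the one with the highest mean over the 6 arrays stood for it. This concerned 6 of the genes named by the fixed rule below, and the probe sets of 1 of them, PSPH, had opposite signs in shp63 ON (−0.34 and 0.08). No filter on dim genes was applied. The gene targeted by the shRNA and some members of the gene lists were not analysed here, so the planned check of the knockdown on the targeted gene was not made. Gene lists are therefore given by their measured members.

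Tests were fixed before the data were examined. A model with 1 mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, 3 residual degrees of freedom before moderation), with no covariates, since the design text names a model of this form. It gave Nutlin-3 against control, shp63 ON against control and shp63 ON against Nutlin-3. P-values were adjusted by the Benjamini-Hochberg method over all 18404 genes, and a gene was called at an adjusted p under 0.05. Fold changes are differences of group means on the log2 scale with limma's standard errors (SE). Each list also has counts after adjustment over its own members. The replicate numbers of the labels were not used as a block in this fit.

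Gene lists numbered 22 and were written before the data were examined: p53 target, mitotic, DNA replication, basal epithelial keratin and adhesion, squamous terminal differentiation, epithelial junction, mesenchymal and TGF-beta response, interferon-stimulated, inflammatory cytokine and NF-kB, sterol and fatty acid synthesis, amino acid and integrated stress response, oxidative phosphorylation, hypoxia and glycolysis, NRF2 antioxidant, H2A.Z and its SRCAP and TIP60 deposition complexes, ribosomal protein, and immediate early and heat shock genes, and markers of mesothelial, stromal fibroblast, leukocyte, endothelial, and airway and alveolar cells. Lists were tested with camera, which asks whether a list shifted relative to the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Beside it stand camera with an estimated correlation and fry (whether a list's genes moved one way, on balance). The percentile of the list's median among 10000 random lists matched on mean level in 20 bins is also given. With a preset correlation camera takes its degrees of freedom from the number of genes. With an estimated one it uses the 3 residual degrees of freedom, so its p-values are larger at any correlation. A further 3 lists were added after seeing the data, and their p-values are adjusted over all 25 lists together, which does not correct for that choice.

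Genes are named by a rule fixed before the data were examined. It takes p53 family genes with a value, MDM2 and CDKN1A, the 8 largest rises and 8 largest falls per comparison with control among called genes whose groups did not overlap, up to 4 called members per list, the 5 genes per direction with the largest change in both comparisons, and the 5 per direction with the largest difference between shp63 ON and Nutlin-3. Small RNA genes and unsettled symbols were passed over. ACTA2, the histone, Fanconi and antigen presentation genes and the neighbours of CENPT were named after their values were seen.

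Both comparisons use the same control arrays. Their overlap is therefore set beside the overlap of independent lists and beside 50 simulated data sets of unchanged groups. After the results were seen, each comparison was also given a control array of its own, both ways round, with the 2 control arrays as groups of their own in the fit, so that the spread came from the Nutlin-3 and shp63 ON pairs alone. The fitting steps were tested on simulated data built from the 18404 genes. For Nutlin-3 against control 89.6% of genes changed by 0.5 on the log2 scale were recovered, for shp63 ON against control 95.5%, and all of those changed by 1 or 2. Of 18164 unchanged genes 18 and 14 were called. The simulated genes varied independently, few were changed and none held a trend with level. These counts therefore do not give the number of false calls in the deposited data.

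Alternatives were quantile normalization, centring of each array on its median, leaving out the 33.3% dimmest genes, the mean of a gene's probe sets, eBayes with a trend or robust, an analysis of variance without moderation, a fit of the compared groups alone, the replicate number as a block, a fold change of at least 1.5, an adjusted p under 0.10, and each array left out in turn. Cyclic loess between arrays was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.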

Results

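H226 is a human lung squamous carcinoma line, here carrying an shRNA against p63 that doxycycline turns on. p63 is a transcription factor of basal and squamous epithelia and belongs to the p53 family. RNA was measured on 6 Affymetrix HuGene 1.0 ST arrays, 2 in each of 3 groups. The control cells grew untreated with the shRNA off. The Nutlin-3 cells, also with the shRNA off, received 10 µM Nutlin-3 for 12 h. Nutlin-3 is a small molecule that blocks MDM2, the ubiquitin ligase that keeps p53 low, and so activates p53. The shp63 ON cells received 1 µg/mL doxycycline for 48 h to turn on the shRNA. Values were log2 intensities of 32321 probe sets, which gave 18404 named genes. Replicate arrays correlated across genes at r = 0.998 in control, 0.997 with Nutlin-3 and 0.997 in shp63 ON, against 0.975 to 0.989 between arrays of different groups. With 2 arrays per group, the number of arrays limits the precision: an exact permutation test of 2 against 2 cannot go below a two-sided p of 0.333, so the p-values below come from limma's model across all genes. The labels do not say that replicates came from separate cultures, so these p-values may measure only technical spread.

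Nutlin-3 raised the genes that p53 is known to activate and lowered the genes that replicate DNA and divide the cell. MDM2 went from 11.40 ± 0.05 (SD, n = 2) in control to 12.70 ± 0.32 (n = 2), a 2.46-fold rise (log2 fold change 1.30, SE 0.14). CDKN1A, the cyclin-dependent kinase inhibitor p21, went from 10.26 ± 0.07 to 11.84 ± 0.01 (n = 2 each, log2 fold change 1.59, SE 0.06). On the DNA replication side, CCNE2, the gene of cyclin E2, went from 9.55 ± 0.01 to 5.61 ± 0.17 (log2 fold change −3.94, SE 0.10). In all, 3410 of 18404 genes passed the threshold, 1774 higher and 1636 lower (limma, Benjamini-Hochberg adjusted p under 0.05). The count fell to 1405 without control replicate 1, to 1656 without control replicate 2 and to 2259 without nutlin replicate 2, with fewer arrays in each fit. Of the 3410, 784 changed by at least 1.5-fold, 456 higher and 328 lower. With each array centred on its median, the split became 2175 higher and 1236 lower.

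Among the p53 target genes, 36 of 42 rose with Nutlin-3, 1 fell and 5 did not pass, with a median log2 fold change of 1.19. Adjusted over the list alone, 39 rose and 1 fell. ABCA12, a lipid transporter of the epidermis, rose most (log2 fold change 2.74, SE 0.06), followed by GDF15, a secreted stress cytokine (2.32, SE 0.08), EDA2R, a receptor of the tumour necrosis factor family (2.00, SE 0.06), and the sestrin SESN1 (1.70, SE 0.09). The member that fell was ACTA2, smooth muscle actin (−0.40, SE 0.10), and it did not pass without control replicate 1 (limma adjusted p = 0.0820, range over alternatives 0.00050 to 0.0998), control replicate 2 (0.0606) or nutlin replicate 2 (0.0579). The shift of the list passed in camera, limma's test of a list against the other genes (Benjamini-Hochberg adjusted p = 9.7e-35, and adjusted p = 0.0415 with an estimated correlation). TP73, the other member of the p53 family with a value here, did not pass (log2 fold change 0.07, SE 0.08).

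Of 34 DNA replication genes, 33 fell and 1 did not pass, both over all genes and adjusted over the list alone (median log2 fold change −1.34). Besides CCNE2, the largest falls were in the origin-licensing factor CDC6 (−3.46, SE 0.24), the helicase subunit GINS2 (−2.91, SE 0.09) and the initiation factor MCM10 (−2.76, SE 0.08). Camera gave an adjusted p of 6.9e-38, and adjusted p = 0.0415 with an estimated correlation. Of 33 mitotic genes, 32 fell by either adjustment and none rose, with a smaller median of −0.68. They included the spindle checkpoint kinase BUB1B (−1.45, SE 0.09), the cytokinesis protein anillin, ANLN (−1.38, SE 0.07), and the condensin subunit NCAPG (−1.22, SE 0.12). The camera call of the mitotic list (adjusted p = 2.4e-23) was lost with an estimated correlation (adjusted p = 0.209).

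The 8 largest rises, beyond ABCA12 and GDF15, were in DNAI3, an axonemal dynein chain (2.44, SE 0.07), the fatty acid hydroxylase CYP4F2 (2.22, SE 0.10), the glycoprotein hormone STC1 (2.13, SE 0.08), FRMPD2 (2.10, SE 0.11), the phospholipid transfer protein PLTP (2.09, SE 0.07) and the efflux transporter ABCC2 (2.05, SE 0.08). CYP4F2 has close paralogs, so its probes may also bind their transcripts. The 8 largest falls were led by FAM111B, a serine protease (−4.40, SE 0.09), and DTL, the substrate receptor of a ubiquitin ligase that degrades the licensing factor CDT1 (−4.16, SE 0.11). WDR76 (−2.96, SE 0.10) and the checkpoint adaptor claspin, CLSPN (−2.54, SE 0.08, or −1.95 as the mean of its 2 probe sets), stood beside CCNE2, CDC6, GINS2 and MCM10.

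Smaller shifts with Nutlin-3 passed in 4 further lists, and each of these calls was lost with an estimated correlation. The NRF2 list lost its call at an estimate of −0.030, under the preset 0.01, so a higher correlation was not the reason. Of 24 NRF2 antioxidant genes, 8 rose and none fell, among them ABCC2 and heme oxygenase HMOX1 (0.67, SE 0.06), with an adjusted p of 0.0041 in camera and adjusted p = 0.209 with an estimated correlation. Of 25 amino acid and integrated stress response genes, 8 rose and 1 fell, with 2 falling when adjusted over the list alone. The stress regulator NUPR1 (1.81, SE 0.07), phosphoserine phosphatase PSPH (0.69, SE 0.09) and the mTORC1 inhibitor DDIT4 (0.63, SE 0.09) were among them (camera adjusted p = 0.0047, and adjusted p = 0.533 with an estimated correlation). Of 21 basal epithelial keratin and adhesion genes, 9 rose and 2 fell, or 9 and 4 adjusted over the list alone. Keratin 15, KRT15 (0.93, SE 0.06), and the laminin-332 chain LAMB3 (0.77, SE 0.07) led them (camera adjusted p = 0.025, and adjusted p = 0.337 with an estimated correlation), and quantile normalization ended this call. Of 22 sterol and fatty acid synthesis genes, 6 fell and none rose, or 7 adjusted over the list alone. The last enzyme of cholesterol synthesis, DHCR7 (−0.60, SE 0.07), and the sterol sensor INSIG1 (−0.58, SE 0.09) were examples (camera adjusted p = 0.0117, and adjusted p = 0.533 with an estimated correlation). Without nutlin replicate 2 the camera adjusted p of that list was 0.0779.

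The other 15 lists did not pass camera with Nutlin-3, although single members changed. In the inflammatory cytokine and NF-kB list, 5 of 25 rose and 2 fell, or 6 and 3 adjusted over the list alone, with rises of the collagenase MMP1 (1.64, SE 0.10) and interleukin 1 beta, IL1B (1.09, SE 0.10). In the epithelial junction list, 2 of 22 rose and 3 fell, or 2 and 7 adjusted over the list alone. The 2 that rose were the desmosomal cadherins DSG3 (2.03, SE 0.06) and DSC3 (0.76, SE 0.07). That list's median was −0.09 and its mean 0.03, while camera pointed down. Hypoxia and glycolysis genes showed 7 rises among 22, including ANGPTL4 (1.40, SE 0.12) and VEGFA (0.67, SE 0.06). Immediate early and heat shock genes showed 5 rises and 2 falls among 20, led by FOS (1.31, SE 0.07) and FOSL1 (0.83, SE 0.08). Of 20 genes for H2A.Z and its SRCAP and TIP60 deposition complexes, 4 fell, among them the histone variant H2AZ1 (−0.91, SE 0.10) and its chaperone ANP32E (−0.73, SE 0.09). Mesenchymal and TGF-beta response genes had 1 rise and 3 falls among 26, with falls of TGFB2 (−0.57, SE 0.06) and N-cadherin, CDH2 (−0.52, SE 0.06). Squamous terminal differentiation genes had 2 rises, CSTA (0.73, SE 0.07) and GRHL3 (0.67, SE 0.07), and 1 fall among 32, which did not pass when adjusted over the list alone.

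Interferon-stimulated genes had 1 fall among 32, oxidative phosphorylation genes 1 rise among 34 that did not pass when adjusted over the list alone, and ribosomal protein genes 1 rise and 1 fall among 33, of which the fall passed when adjusted over the list alone. Among the markers of other cell types, 1 of 10 mesothelial genes rose, the zinc finger gene BNC1 (0.68, SE 0.06), and 2 of 13 leukocyte genes rose, LAPTM5 (0.89, SE 0.06) among them. Of 10 endothelial genes, 1 rose and 2 fell, or 1 and 3 adjusted over the list alone, 2 of 10 airway and alveolar genes fell, and none of 13 stromal fibroblast genes passed in limma at an adjusted p under 0.05. For the lists with no second count given here, counts adjusted over the list alone were the same. The inflammatory, H2A.Z and leukocyte lists had medians and means of opposite sign (−0.02 and 0.12, 0.03 and −0.06, and −0.04 and 0.05), and camera followed the mean in each.

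**Figure D1:**
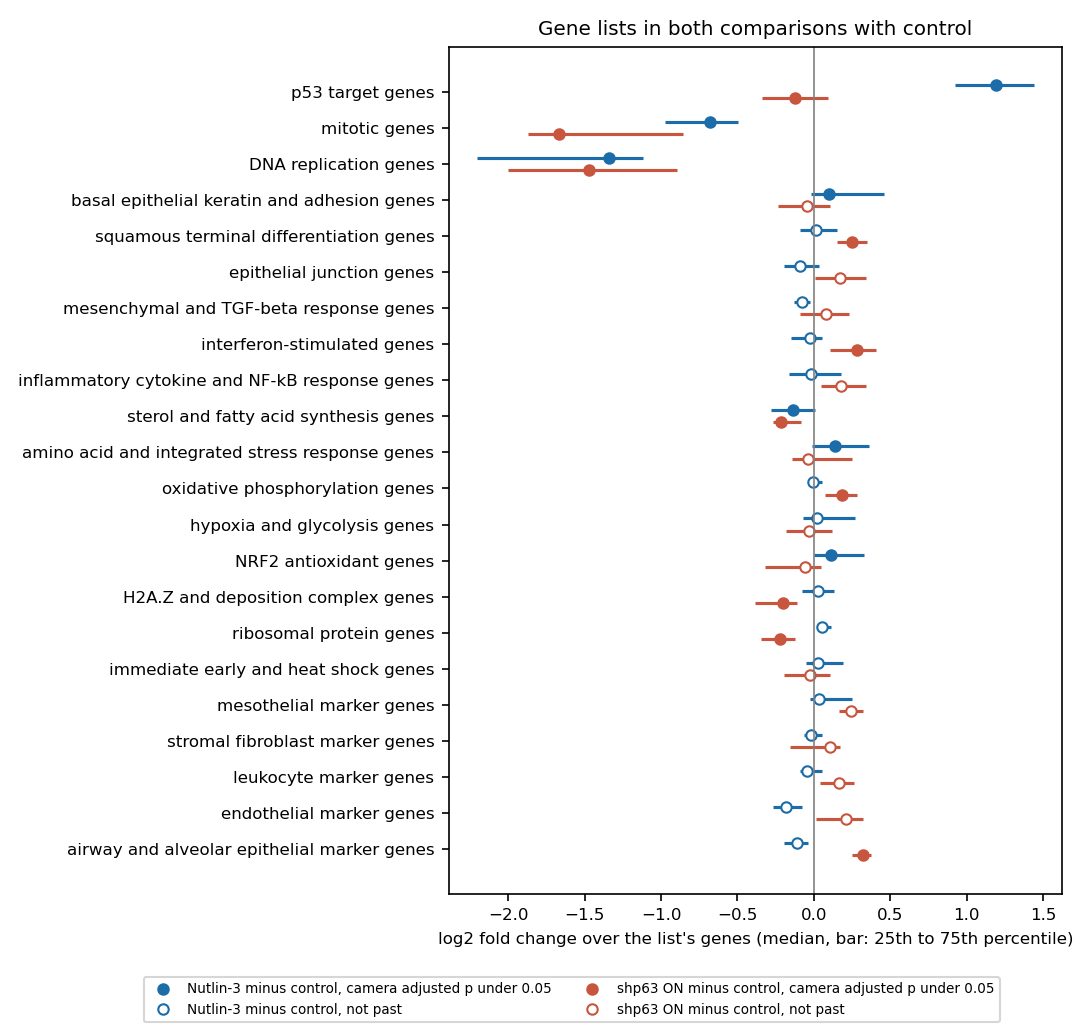
Median log2 fold change (points) and 25th to 75th percentile (bars) of the genes of each of the 22 lists, for Nutlin-3 against control (blue) and shp63 ON against control (red), with filled points where camera gave an adjusted p under 0.05. The p53 target genes lie at 1.19 with Nutlin-3 and −0.12 in shp63 ON, and the DNA replication genes at −1.34 and −1.47.

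With the p63 shRNA turned on, DNA replication and mitotic genes were also lower, while the p53 target genes as a list did not rise. MKI67, the proliferation antigen Ki-67, fell (log2 fold change −2.23, SE 0.09, n = 2 each), as did the mitotic kinase CDK1 (−2.46, SE 0.14). CDKN1A stood at 10.39 ± 0.00 (SD, n = 2) against 10.26 ± 0.07 in control and did not pass (log2 fold change 0.13, SE 0.06, limma adjusted p = 0.150). It passed as higher with a trend in eBayes (limma adjusted p = 0.0461) and in the analysis of variance without adjustment. MDM2 stood at 10.98 ± 0.09, a fall (log2 fold change −0.43, SE 0.14, limma adjusted p = 0.0455) that was no longer past the threshold in 8 of 16 alternatives, with adjusted p from 0.0058 to 0.229. The cytokine genes IL1B (−3.07, SE 0.10) and IL1A (−2.65, SE 0.08) were among the largest falls. In all, 6670 of 18404 genes passed, 3634 higher and 3036 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Fewer genes passed without any 1 control or shp63 ON array. Falls then outnumbered rises without control replicate 1, control replicate 2 or shp63_on replicate 1, but not without shp63_on replicate 2. The median log2 fold change over all genes stayed positive in these fits (0.048, 0.033, 0.038 and 0.040, in this order). The balance of called rises and falls thus turned with the arrays used. It also turned at a change of at least 1.5-fold, with 314 higher and 858 lower. The gene that the shRNA targets was not analysed here, so the depth of the knockdown is not given. Doxycycline was given to the shp63 ON cells alone and for longer than Nutlin-3 was, and no array held another shRNA. The drug, its duration, other effects of the shRNA and the knockdown thus cannot be separated in this comparison.

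Many of the rises were small and followed the level of the gene. Genes with a mean log2 intensity of 6 to 7 had a median log2 fold change of 0.17 in shp63 ON, and 1098 of 3167 rose, whereas genes at 8 to 9 had a median of −0.06 and 501 of 2950 rose. Cyclic loess normalization, chosen after seeing the data because it removes such a trend, left 2456 higher and 3003 lower. The lists below are therefore given with the count after cyclic loess where it moved by over 1.5 times.

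**Figure D2:**
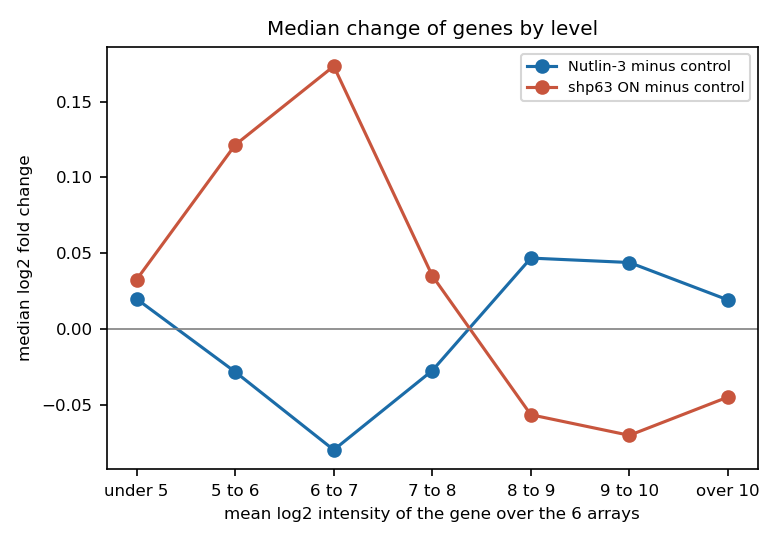
Median log2 fold change (vertical axis) of the genes in each band of mean log2 intensity over the 6 arrays (horizontal axis), for Nutlin-3 against control (blue) and shp63 ON against control (red). The shp63 ON line peaks at 0.17 in the band from 6 to 7, where the Nutlin-3 line is at −0.08.

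Of 34 DNA replication genes, 33 fell in shp63 ON, with a median log2 fold change of −1.47, and the same number fell when adjusted over the list alone. MCM10 (−2.39, SE 0.08), CDC6 (−2.38, SE 0.24), CCNE2 (−2.33, SE 0.10) and GINS2 (−2.30, SE 0.09) fell most. The camera adjusted p was 6.4e-29, and adjusted p = 0.117 with an estimated correlation. The estimate for this list was 0.069. The second p-value also rests on only 3 residual degrees of freedom, so it does not measure correlation between the genes alone. The same holds for every list given with an estimated correlation. Of 33 mitotic genes, 31 fell and 2 did not pass, or 32 fell adjusted over the list alone, with a median of −1.67. The topoisomerase TOP2A (−2.14, SE 0.09) and NCAPG (−2.13, SE 0.12) followed CDK1 and MKI67 (camera adjusted p = 2.4e-27, and adjusted p = 0.224 with an estimated correlation).

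The squamous, interferon and airway lists shifted up in shp63 ON by camera, with calls lost at an estimated correlation. For the squamous list the estimate was 0.0042, under the preset 0.01, so a higher correlation was not the reason for its loss. Of 32 squamous terminal differentiation genes, 16 rose, 1 fell and 15 did not pass, or 17 and 1 adjusted over the list alone, with a median of 0.25. Filaggrin, FLG (1.06, SE 0.14), keratin 13, KRT13 (0.75, SE 0.07), and the transcription factor OVOL1 (0.65, SE 0.07) rose, whereas the protease inhibitor CSTA fell (−0.86, SE 0.07). Camera gave an adjusted p of 0.00031, and adjusted p = 0.224 with an estimated correlation. After cyclic loess 9 rose and 1 fell. Of 32 interferon-stimulated genes, 14 rose, 1 fell and 17 did not pass, or 17 rose and 1 fell adjusted over the list alone, with a median of 0.28. SAMD9L, a cytoplasmic antiviral protein, rose most (1.43, SE 0.08), with the RNA sensor RIGI (0.54, SE 0.07) and the transcription factor IRF7 (0.50, SE 0.06). Camera gave an adjusted p of 0.00061, and adjusted p = 0.351 with an estimated correlation. After cyclic loess 9 rose and 1 fell. The genes of both lists lay on average in the band from 6 to 7, where the median of all genes was above 0, at mean log2 intensities of 6.58 and 6.79, as did the airway and alveolar markers at 6.48. Of 10 such markers, 8 rose and none fell, or 9 adjusted over the list alone, with a median of 0.32. The secretoglobin SCGB3A1 (0.82, SE 0.08) and the alveolar receptor AGER (0.57, SE 0.08) were among them (camera adjusted p = 0.0014, and adjusted p = 0.280 with an estimated correlation). After cyclic loess 2 rose. The medians of the squamous, interferon and airway lists lay at percentiles 99.9, 100 and 98.5 of random lists matched on level. Camera still passed after cyclic loess, with an adjusted p of 0.0042 (range over 13 alternatives 0.00016 to 0.0050), 0.0019 (7.8e-06 to 0.0047) and 0.0158 (0.00064 to 0.0158).

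In 3 further lists the shift was down in shp63 ON and in 1 it was up, with many members not passing. Of 33 ribosomal protein genes, 18 fell, 2 rose and 13 did not pass, or 21 and 2 adjusted over the list alone, with a median of −0.22. RPS24 (−0.73, SE 0.08) and RPL23 (−0.60, SE 0.07) fell most (camera adjusted p = 1.1e-06, and adjusted p = 0.280 with an estimated correlation). Of 22 sterol and fatty acid synthesis genes, 9 fell, none rose and 13 did not pass, or 12 fell adjusted over the list alone, with a median of −0.21. The desaturase FADS1 (−0.89, SE 0.10), fatty acid synthase FASN (−0.65, SE 0.07) and squalene epoxidase SQLE (−0.65, SE 0.08) were examples (camera adjusted p = 0.00031, and adjusted p = 0.345 with an estimated correlation). After cyclic loess 5 fell. Of 20 genes for H2A.Z and its SRCAP and TIP60 deposition complexes, 8 fell, none rose and 12 did not pass by either adjustment, with a median of −0.20. The histone variant H2AZ1 (−1.02, SE 0.10) and the ATPase RUVBL1 (−0.89, SE 0.06) fell most (camera adjusted p = 0.00029, and adjusted p = 0.297 with an estimated correlation). Of 34 oxidative phosphorylation genes, 14 rose, 1 fell and 19 did not pass by either adjustment, with a median of 0.19, including the complex I subunit NDUFA1 (0.45, SE 0.08) and the complex III subunit UQCRC1 (0.40, SE 0.07). Camera gave an adjusted p of 0.0018, and adjusted p = 0.345 with an estimated correlation.

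The p53 target genes moved slightly down in shp63 ON. Of 42, 19 fell, 4 rose and 19 did not pass by either adjustment, with a median of −0.12. The lysosomal protein DRAM1 fell most, from 10.37 ± 0.01 in control to 9.38 ± 0.10 (SD, n = 2 each), before the growth factor KITLG (−0.98, SE 0.10), ABCA12 (−0.84, SE 0.06) and CYFIP2 (−0.76, SE 0.07). Camera gave an adjusted p of 0.0054, and adjusted p = 0.345 with an estimated correlation. Quantile normalization, cyclic loess and leaving out the dimmest genes each ended this call, and the median lay at percentile 4.61 of 10000 random lists matched on level.

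The largest rises were in TMPRSS11E, a serine protease of stratified epithelia (3.25, SE 0.13), ANKRD22 (3.06, SE 0.11), the nucleoside transporter SLC28A3 (2.70, SE 0.14), the centromere protein CENPT (2.54, SE 0.06), the collagenase MMP13 (2.30, SE 0.10), the imprinted gene PEG10 (2.09, SE 0.07), the HLA region transcript HCP5 (2.02, SE 0.08) and the adhesion molecule CEACAM6 (1.91, SE 0.20). The largest falls were in the histone genes H2BC14 (−3.24, SE 0.11) and H1-5 (−2.69, SE 0.14), IL1B, IL1A, the PCNA-binding factor PCLAF (−2.62, SE 0.08), FEZ1 (−2.55, SE 0.07), DTL (−2.53, SE 0.11) and the cohesin acetyltransferase ESCO2 (−2.53, SE 0.07). TMPRSS11E and PCLAF each have 2 probe sets that differ in size of change, and with their means taken TMPRSS11E rose by 2.34, less than ANKRD22, SLC28A3 and CENPT, and PCLAF fell by 1.81. Histone genes share much sequence, so a probe set for 1 of them may also bind others.

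The other 12 lists did not pass camera in shp63 ON, although single members changed. Of 22 epithelial junction genes, 10 rose and 2 fell, including matriptase, ST14 (1.04, SE 0.06), and claudin 4, CLDN4 (0.77, SE 0.10), with a fall of DSG3 (−0.73, SE 0.06). Quantile normalization, cyclic loess and leaving out the dimmest genes each brought that list past the threshold. In the inflammatory list, 9 of 25 rose and 4 fell, among them CXCL8 (1.07, SE 0.13) and MMP1 (−0.97, SE 0.10), and its median was 0.18 but its mean −0.07, with camera pointing up. Of 24 NRF2 antioxidant genes, 3 rose and 8 fell, with the glutathione peroxidase GPX2 (−1.06, SE 0.10) and the cystine transporter SLC7A11 (−0.74, SE 0.07) lowest. Of 21 basal epithelial keratin and adhesion genes, 5 rose and 6 fell, led by integrin beta 4, ITGB4 (−0.75, SE 0.06), and CD44 (−0.65, SE 0.08). Mesenchymal genes had 6 rises and 4 falls among 26, or 7 and 4 adjusted over the list alone, with a fall of SNAI2 (−0.53, SE 0.06). Amino acid and stress response genes had 7 rises and 5 falls among 25, or 7 and 6 adjusted over the list alone, with a fall of MTHFD2 (−0.95, SE 0.06). Hypoxia and glycolysis genes had 4 rises and 5 falls among 22 (5 and 3 after cyclic loess), with falls of PDK1 (−0.70, SE 0.07) and PFKFB3 (−0.69, SE 0.06). Immediate early and heat shock genes had 3 rises and 5 falls among 20, or 5 and 6 adjusted over the list alone and 4 and 3 after cyclic loess, with NR4A1 higher (0.66, SE 0.08) and EGR1 lower (−0.64, SE 0.07). Of the markers of other cell types, 5 of 10 mesothelial genes rose and 1 fell (3 and 1 after cyclic loess), led by MUC16 (0.90, SE 0.12), 3 of 13 leukocyte genes rose and none fell, led by CD68 (0.75, SE 0.06), 4 of 10 endothelial genes rose and none fell (2 and 1 after cyclic loess), led by CDH5 (0.57, SE 0.08), and 3 of 13 stromal fibroblast genes rose and 2 fell (0 and 1 after cyclic loess and limma). Where no second count is given, counts adjusted over the list alone were the same.

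**Figure D3:**
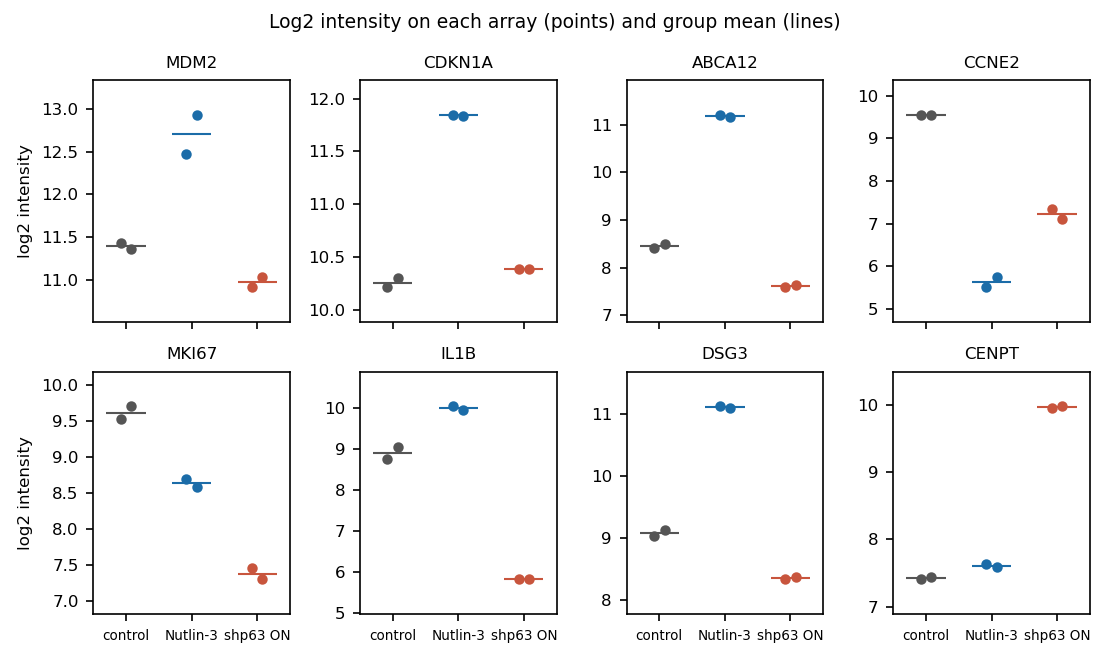
Log2 intensity (vertical axis) of 8 genes on each array (points, 2 per group) with group means (lines) in control, Nutlin-3 and shp63 ON, each panel on its own scale, which does not start at 0. MDM2 and CDKN1A are highest with Nutlin-3, at means of 12.70 and 11.84, MKI67 is lowest in shp63 ON, and CENPT is high in shp63 ON alone, at 9.96.

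Mitotic and DNA replication genes fell in both responses, whereas the p53 target genes rose as a list with Nutlin-3 alone. Of 67 mitotic and DNA replication genes, 63 fell in both comparisons with control. Across all genes, 562 fell in both and 220 rose in both. Without control replicate 1 these were 363 and 73, and without control replicate 2 they were 341 and 84, with fewer arrays in each fit. Independent lists of these sizes would share 269.9 and 350.3, and unchanged groups simulated against the same control arrays shared 0 in each of 50 sets by limma, but these groups hold no effects, so the simulation does not test lists of these sizes. The genes that fell most in both were DTL, MCM10, CDC6, PCLAF (−2.36, SE 0.08, with Nutlin-3, or −1.77 as the mean of its 2 probe sets) and CCNE2. Rises in both were smaller, led by APOBEC3H, a cytidine deaminase (1.20 with Nutlin-3 and 0.78 in shp63 ON, SE 0.09 each), CYRIA (0.88 and 0.77, SE 0.07 each), CLTRN (0.89 and 0.77, SE 0.06 each), the B cell adaptor BLNK (0.79 and 0.76, SE 0.07 each) and GALNT5 (0.75 and 0.87, SE 0.07 each). At a change of at least 1.5-fold in each, 242 genes fell in both and 10 rose in both.

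Other genes went opposite ways: 544 rose with Nutlin-3 and fell in shp63 ON, where independent lists would share 292.6, and 535 fell with Nutlin-3 and rose in shp63 ON, where they would share 323.0. At a change of at least 1.5-fold in each, 49 and 7 did. Among the former were IL1B, DSG3, CSTA, MMP1 and ABCA12. The comparisons had opposite trends with level, which independent lists ignore. At mean log2 intensities of 6 to 7 the medians were −0.08 with Nutlin-3 and 0.17 in shp63 ON, and at 8 to 9 they were 0.05 and −0.06. After cyclic loess the opposite-way counts over all genes were 516 and 446. With a control array of its own for each comparison both counts were lower, as were those of independent lists. Of the 36 p53 target genes that rose with Nutlin-3, 19 fell in shp63 ON, 2 rose and 15 did not pass. The correlation of log2 fold changes across genes was 0.11, against 0.50 in simulated unchanged groups, and 44.0% of genes had the same sign, against 66.8%. The simulated groups hold no effects, so their correlation and shared signs come from the shared control arrays alone. They are no baseline for groups with effects, and nothing is concluded from these differences. Genes are not independent replicates. The covariance was 0.0113 against a simulated 0.0037, a difference of 0.0076. With a control array of its own for each comparison, a split chosen after the results were seen, it was 0.0035 or 0.0107. These values rest on 1 control array per comparison, and part of the overlap with both control arrays may come from sharing them.

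**Figure D4:**
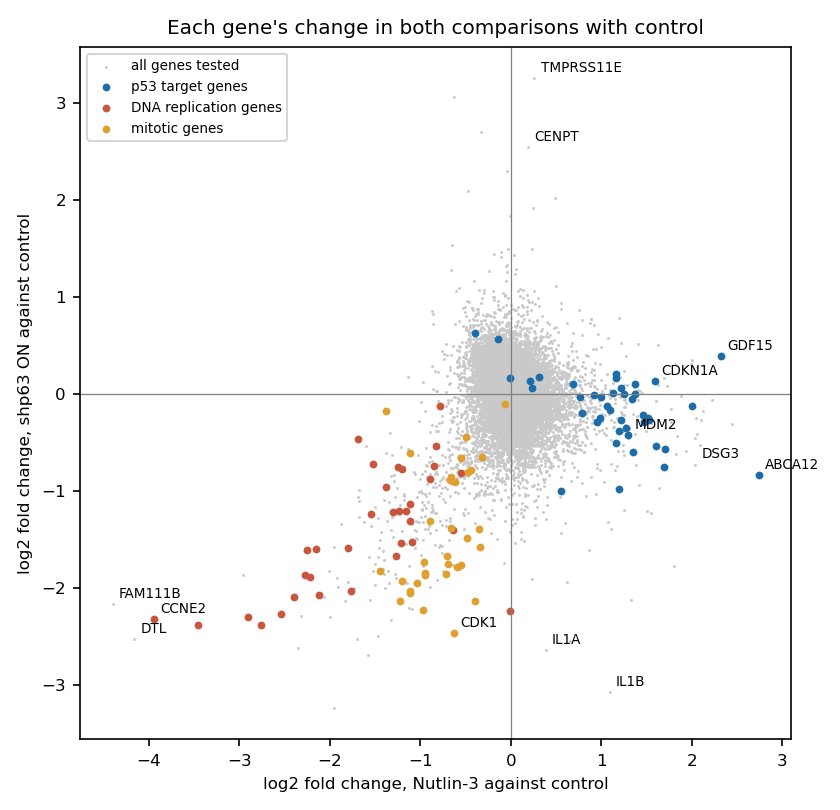
Log2 fold change of each of 18404 genes with Nutlin-3 (horizontal axis) and in shp63 ON (vertical axis), both against control, with p53 target (blue), DNA replication (red) and mitotic (yellow) genes coloured. The DNA replication and mitotic genes lie at the lower left, and 36 of 42 p53 target genes lie to the right, where they had risen with Nutlin-3.

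The direct comparison of shp63 ON with Nutlin-3 asked whether the responses differed gene by gene. The control arrays entered it only through the estimate of the spread. Of 42 p53 target genes, 36 were lower in shp63 ON than with Nutlin-3, 2 were higher and 4 did not pass. The camera adjusted p of that list was 2.1e-19, and adjusted p = 0.191 with an estimated correlation. Of 33 mitotic genes, 25 were lower in shp63 ON and 2 higher (camera adjusted p = 5.1e-09, and adjusted p = 0.329 with an estimated correlation). Of 34 DNA replication genes 18 were higher and 5 lower, but the list did not pass (camera adjusted p = 0.0516, and adjusted p = 0.409 with an estimated correlation). The largest differences downward were in IL1B (−4.17, SE 0.10), RGS2, a regulator of G protein signalling (−3.58, SE 0.08), ABCA12 (−3.58, SE 0.06), the calcium-binding protein S100A2 (−3.46, SE 0.13) and FEZ1 (−3.20, SE 0.07). Upward they were in ANKRD22 (3.69, SE 0.11), SLC28A3 (3.03, SE 0.14), TMPRSS11E (2.99, SE 0.13, or 2.16 as the mean of its 2 probe sets), PEG10 (2.56, SE 0.07) and CENPT (2.36, SE 0.06). In all, 9481 genes passed, 5057 higher and 4424 lower in shp63 ON (limma, Benjamini-Hochberg adjusted p under 0.05). The balance turned with each array centred on its median (4243 higher and 5201 lower), after cyclic loess (3958 and 4334), without the dimmest genes (3652 and 4282) and among the 2412 that differed by at least 1.5-fold (1099 and 1313). Treatment lengths differed between these groups as well, 48 h against 12 h.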

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

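No test in this part was chosen after its result was seen. The comparisons above leave out 13163 probe sets that name no gene or several genes, and these were fitted on their own in the same limma model. With Nutlin-3, 33 of them passed against control at an adjusted p under 0.05, 21 higher and 12 lower. In shp63 ON, 480 passed against control, 153 higher and 327 lower. They stand out only as signal in probe sets that no comparison above used, and no explanation of either count was tested.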

How the results depend on the processing

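Cyclic loess and the separate control arrays were chosen after the results were seen, and every other setting here before. Results are given as counts at an adjusted p under 0.05 for Nutlin-3 against control (3410 genes), shp63 ON against control (6670), shp63 ON against Nutlin-3 (9481) and genes changed the same way in both comparisons with control (782), in this order. The analysis of variance without moderation called 1236, 3003, 6089 and 337, a loss that goes with its 3 residual degrees of freedom, and at an unadjusted p under 0.05 it gave 1243 genes changed the same way in both. A fold change of at least 1.5 left 784, 1172, 2412 and 252, fewer by construction. In camera, 7 lists shifted with Nutlin-3 and 10 in shp63 ON. With an estimated correlation these became 2 and 0, and with fry, which asks another question, 13 and 17. A higher correlation does not account for every loss. The estimate was −0.030 for the NRF2 list with Nutlin-3 and 0.0042 for the squamous list in shp63 ON. Both lie under the preset 0.01, yet both calls were lost. With an estimated correlation camera also rests on the 3 residual degrees of freedom, which raises its p-values at any correlation. Both losses go with that. How much it contributed to the other losses was not tested.

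Leaving out each array in turn gave 1405 to 2991 genes with Nutlin-3, 3454 to 6960 in shp63 ON and 425 to 647 changed the same way in both, with fewer samples in each fit and a lone array assumed to vary like the other groups. Without control replicate 1 the counts were 1405, 3932 and 436, and without control replicate 2 they were 1656, 3454 and 425. Nutlin-3 calls fell to 2259 without nutlin replicate 2, and shp63 ON calls to 4139 without shp63_on replicate 1. Calls of lists that did not pass appeared without single arrays: endothelial markers with Nutlin-3 without control replicate 2 (camera adjusted p = 0.0335, range over 13 alternatives 0.0308 to 0.156) or nutlin replicate 2 (0.0308), hypoxia genes with Nutlin-3 without control replicate 2 (0.0495, range 0.0495 to 0.244), and in shp63 ON mesothelial markers without control replicate 2 (0.0261, range 0.0261 to 0.239) or shp63_on replicate 2 (0.0380) and leukocyte markers without control replicate 1 (0.0470, range 0.0463 to 0.228) or shp63_on replicate 1 (0.0463). The sterol synthesis call with Nutlin-3 was lost without nutlin replicate 2 (0.0779, range 0.00078 to 0.0779). Of 221 named values, 34 fell below the threshold without control replicate 1, 34 without control replicate 2, 13 and 10 without nutlin replicates 1 and 2, and 17 and 12 without shp63_on replicates 1 and 2.

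With the replicate number as a replicate block the counts were 3097, 6530, 9405 and 726, with 8 and 11 lists, the added ones being endothelial markers with Nutlin-3 (camera adjusted p = 0.0403, range over 13 alternatives 0.0308 to 0.156) and mesothelial markers in shp63 ON (0.0450, range 0.0261 to 0.239). Deviations of same-numbered arrays from their group means correlated across genes at −0.06, −0.02 and 0.11, so the numbers are not shown to pair the arrays. With a control array of its own for each comparison, 387 genes changed the same way in both (Nutlin-3 against control replicate 1) or 393 (against control replicate 2), where the spread of the lone control arrays is taken from the pairs of the other groups, so no call is rested on these counts. Every other alternative kept each count within 1.5 times. No named gene changed its direction past the threshold under any alternative. Of the named values, quantile normalization took 9 below the threshold, cyclic loess 10, and the analysis of variance with adjustment 55. No alternative was run for the gene that the shRNA targets, because it was not analysed here. Signal over background could not be judged, since the values carry no detection call, so small changes of dim genes rest on the normalization.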

Other observations

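The cyclic loess test of CENPT, every other cyclic loess value in this part and the 3 gene lists of the next 2 paragraphs were chosen after the results were seen. All other tests in this part were written down before.

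Genes of homologous recombination and the Fanconi pathway, which repair broken and crosslinked DNA, fell in both comparisons with control. Camera p-values of these lists are adjusted together with the 22 lists above, and with an estimated correlation none of them passed. With Nutlin-3, 16 of 20 fell and 1 rose (median log2 fold change −0.98, camera adjusted p = 4.2e-15, and adjusted p = 0.0998 with an estimated correlation). In shp63 ON, 18 fell and none rose (median −0.86, camera adjusted p = 9.9e-15, and adjusted p = 0.154 with an estimated correlation). The recombination factor XRCC2 fell by 2.32 with Nutlin-3 and by 2.29 in shp63 ON (SE 0.07 each), and BRCA1 by 1.51 and 1.75 (SE 0.06 each). RAD51C went the other way with Nutlin-3: its mean was 8.16 in control, 9.66 there and 6.95 in shp63 ON, and the direct difference passed (limma adjusted p = 2.1e-05, both shp63 ON arrays below both Nutlin-3 arrays). Of 43 replication-dependent histone genes, 24 fell with Nutlin-3 (median −0.43, camera adjusted p = 4.2e-15, and adjusted p = 0.245 with an estimated correlation) and 33 in shp63 ON (median −0.54, camera adjusted p = 4.3e-19, and adjusted p = 0.199 with an estimated correlation), and none rose. H4C13 fell by 0.90 and 1.99 (SE 0.08 each). These genes share sequence, so their probe sets are not independent.

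Some antigen presentation and guanylate-binding protein genes rose in shp63 ON. Of 16 measured, 7 rose, none fell and 9 did not pass (median 0.22, camera adjusted p = 0.0076, and adjusted p = 0.199 with an estimated correlation), against 2 that rose with Nutlin-3 (median −0.02, camera adjusted p = 0.818). In the direct comparison with Nutlin-3, 9 were higher and 3 lower in shp63 ON, and the list did not pass (camera adjusted p = 0.0666). The interferon-induced GTPase GBP2 rose by 1.23 (SE 0.07), the class I regulator NLRC5 by 0.65 (SE 0.06) and beta-2 microglobulin, B2M, by 0.61 (SE 0.07). After cyclic loess 7 rose.

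Genes of middle and low level were higher in shp63 ON, with a median log2 fold change of 0.17 at mean levels of 6 to 7. If the normalization had left a difference between arrays that follows the level, probe sets naming no gene should have shifted alike. Their median in that band was 0.0646, between the bounds set beforehand for and against, so this could not be told apart from a change of the named genes. Cells of another type were not excluded either: the highest of the 5 marker lists, the mesothelial one, lay at percentile 98.9 of random lists matched on level, with airway at 98.5 and endothelial at 98.2. A change of these genes within the line itself would give the same percentiles, so they cannot tell whether other cells were present. The knockdown itself stays open and was not tested.

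CENPT rose by 2.54 in shp63 ON (SE 0.06), in both arrays, and by at least 2.52 under every alternative run. The largest median change of any level band in shp63 ON was 0.17, so a trend with level was too small to give this rise. After cyclic loess the change of CENPT was 2.58. Removing so small a trend could hardly have given another result, so this test adds no support. A vector inserted near the gene could raise its neighbours too: among the 5 measured genes on either side the largest change was 0.48, in C16orf86, while the adjacent TSNAXIP1 was at 0.38 and THAP11 at −0.36 (not passing without control replicate 2, limma adjusted p = 0.0805, range over alternatives 0.0051 to 0.0966, or shp63_on replicate 1, 0.0713). This largest change lies between the bounds set beforehand, so an insertion cannot be told apart from an effect of the knockdown or of doxycycline. With Nutlin-3 CENPT did not pass, at 0.19 (limma adjusted p = 0.0747).

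The p53 target genes fell slightly in shp63 ON, 19 of 42 with a median of −0.12. Their median lay at percentile 4.61 of random lists matched on level, above the bound set beforehand, so a level-dependent difference between arrays may account for the shift of the list. After cyclic loess 13 fell and 4 rose, and the camera adjusted p was 0.196 (range over 13 alternatives 0.0047 to 0.196). Single genes held: DRAM1 was at −0.93, KITLG at −1.12 and ABCA12 at −0.77 after cyclic loess. The number of arrays given doxycycline without the shRNA turned on was 0, so doxycycline itself cannot be told apart from the knockdown.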
